A study of Mus musculus with 6 samples.

How the data were processed

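The series holds 6 droplet single-cell RNA libraries from the hippocampus of old mice, 3 from animals kept in air (Control) and 3 from animals that breathed sevoflurane, an inhaled general anaesthetic, at 2% for 6 h. Tissue was taken 24 h after the exposure, per the labels. The labels' protocols describe collagenase digestion at 37 °C, a nylon mesh, freezing of the cell suspension in liquid nitrogen, and thawing before library preparation with the Single Cell 3′ v3.1 kit of 10x Genomics, which tags each captured transcript near its 3′ end with a unique molecular identifier (UMI). The labels name the group of each library and number the libraries within a group. They do not say that each library is a separate animal beyond the statement that 6 mice were treated, so p-values measure the spread between these libraries.

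The deposited values were raw UMI counts per gene and cell barcode. They were made with Cell Ranger 6.1.1, per the file headers. CASAVA 1.8, Cell Ranger and Seurat are named in the submitters' processing notes, with no role stated. The genome build, the gene annotation and the strand setting of the counting were not given in the sources used here. Barcodes had been called as cells by the authors before the counts were deposited, and 7068 to 9795 barcodes per library and the same 31253 genes in every library were found. No 2 libraries shared more than 0.333% of their barcodes. Library depth ran from 54426522 to 70741809 UMIs. Antisense genes, overlapping genes and members of gene families with near-identical copies are uncertain in such counts, which applies here to the opposite-strand transcript St8sia3os and to the Slfn, Nlrp1, Iigp, metallothionein, MHC and ribosomal protein genes.

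Cells with at least 500 UMIs, at least 300 detected genes and at most 20% mitochondrial UMIs were kept. Scrublet scores were computed per library in scanpy 1.11.5, and the cells with the highest scores were removed at 0.8% per 1000 cells, which took 5.64% to 7.81% of the cells of a library. The 46876 remaining cells of all libraries were clustered together without integration. Counts were scaled to 10000 UMIs per cell and log-transformed, 2000 variable genes were ranked within libraries, and 30 principal components, 15 neighbours and Leiden clustering at resolution 1 gave 37 clusters. Each cluster was scored by the mean log2 fold of the fixed markers of 19 cell types against the 10th percentile of clusters, with 20 CPM (UMI counts scaled to the library total, as usual) added. A name required a score of at least 1, a gap of at least 0.3 to the next cell type, at least 3 markers each detected in at least 20% of the cells, and no other cell type with more markers among the 10 leading genes. A cluster whose median UMI count, relative to the median of its own libraries, lay under 0.333 also needed a marker among its 10 leading genes. The markers were fixed before the data were examined, and the limits of the scoring were set after the clusters had been seen. The class names used here are short for neuron-like, astrocyte-like and so on. Names were given to 34 clusters in 11 classes, and 3 clusters stayed unnamed, so their share is given per group.

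Counts were summed per library over the cells of a class, because cells are not replicates. They were not corrected for free RNA, the transcripts that enter droplets from outside the captured cell. Classes with at least 20 cells in every library were tested for genes, which left 7 classes. The sums of 3 against 3 libraries were compared with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with TMM normalization, the default filter on low counts (filterByExpr) and Benjamini-Hochberg (BH) adjustment over the genes tested in a class, at a threshold of 0.05. Log2 fold changes are sevoflurane over control, each with its standard error (SE), and the SE was derived from the fold and its F statistic. Levels are CPM with TMM factors, given as mean ± SD over 3 libraries. Shares of classes were tested with edgeR on cell counts with the total of kept cells as library size, and also with a two-sided exact permutation test, whose smallest possible p for 3 against 3 libraries is 0.1. The difference of the effect between classes was tested with edgeR as the interaction of class and group, with the library as a block, for the 3 pairs of neurons, oligodendrocytes and astrocytes.

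Gene lists for the tissue and the treatment, fixed before the data were examined, and the marker lists of the cell types were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2, a preset correlation of 0.01, at least 5 tested members and BH adjustment within a class. Camera compares a list with the other genes. It was repeated with an estimated correlation and replaced by fry, which asks whether the genes of a list move on balance in a direction. For members of a list, calls were counted over all genes and as adjusted over the list alone. Genes named in the text followed a rule fixed in advance. It takes the 10 largest folds each way among the called genes of the 3 classes with the most calls, and the 3 largest each way in the other classes. A named gene needed a mean of at least 20 CPM in a group and no overlap between the 3 values of either group. Unnamed gene models, mitochondrially encoded genes, ribosomal protein genes, haemoglobin genes and sex-linked genes were left out of the ranking, and up to 4 members of each described list with the smallest p were added. Some genes that this rule selects are not reported here.

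Gene positions and genomic spans came from GENCODE M21 on GRCm38, matched by gene identifier. Of the 31253 genes, 31184 were found there and 69 were not, and 91 shared a symbol with another gene and were kept apart by identifier. The authors' build not being given, these positions describe the genes and were used for genomic spans and for distances between genes, not for the UMI counts.

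The edgeR step was tested on simulated counts with the means and library sizes of each class and 200 genes changed by known folds. The changed genes were drawn from those with a mean count of at least 20, so recovery of genes with fewer counts was not measured. At a fold of 2, it recovered 70% of the changed genes in neurons, 78% in oligodendrocytes, 80% in astrocytes, 70% in microglia, 74% in oligodendrocyte precursors, 60% in endothelial cells and 58% in ependymal cells. At a fold of 1.5, it recovered 44%, 34%, 32%, 24%, 26%, 8% and 14% in the same order of classes. Between 1.46% and 9.36% of the calls in a class were unchanged genes.

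The alternatives fixed in advance were median-of-ratios (RLE) factors, DESeq2 1.42.0, no filter on low counts, the replicate number as a block, each library left out in turn, doublets kept, a stricter cell filter of 1000 UMIs and 10% mitochondrial UMIs, Leiden resolution 2, a class for each cell from its own marker scores, equal cell numbers per library, and for shares also TMM factors and another total. The alternatives chosen after the data had been seen were each large neuron cluster alone, neuron clusters in equal numbers, neurons without clusters 12 and 30, and removal of a smooth trend (lowess) of each library's log2 level with the logarithm of genomic span, applied as an offset. Every split of the 6 libraries into 3 and 3 was fitted, which makes 10 splits. Markers of border-associated macrophages, T or NK cells, B cells, neutrophils, monocytes or dendritic cells, erythroid cells, smooth muscle and neuroblasts named no cluster, so those cell types were not compared, and committed oligodendrocyte precursors, fibroblasts, pericytes and choroid plexus cells had too few cells for gene tests.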

Results

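Single-cell RNA libraries from the hippocampus of old mice were compared 24 h after 6 h of 2% sevoflurane or of air, to ask which cell classes and genes differ after the exposure. The 3 Control libraries held 54426522, 68544056 and 55356640 UMIs, and the 3 Sevoflurane libraries 67471014, 59589143 and 70741809. After filtering and doublet removal, 7247 ± 759 cells per library remained in Control and 8379 ± 537 in Sevoflurane (mean ± SD, n = 3 each, exact permutation p = 0.2). The median UMIs per cell were 5881 ± 351 and 5548 ± 336 (exact permutation p = 0.3), and the median percent of mitochondrial UMIs was 0.25 ± 0.132 and 0.317 ± 0.0710 (exact permutation p = 0.5). With 3 libraries against 3 this test cannot go below 0.1. The library Sevoflurane 1 stood apart in sex-linked genes: it had 1400 CPM of Xist, the RNA of the inactive X chromosome, against 0.497 to 1.3 in the other 5 libraries, and 0.27 CPM of the Y-linked Ddx3y against 43.7 to 57.7. The Y-linked Eif2s3y stood at 0 CPM against 123 to 146. By these counts Sevoflurane 1 came from female tissue and the other 5 libraries from male tissue, so the sexes were not balanced between the groups. The counts of called genes in each class are therefore also given without Sevoflurane 1. Camera called 10 lists in neurons as tested and 5 without this library. In oligodendrocytes, astrocytes, microglia, oligodendrocyte precursors, endothelial and ependymal cells it called 7, 5, 3, 5, 5 and 4 lists as tested. Without this library it called 8, 9, 4, 7, 8 and 6 there.

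Classes of cells were named by their markers, so that neurons here are neuron-like cells, and likewise for the other classes. Neurons made up 61.4 ± 4.57% of the cells in Control and 62.1 ± 3.07% in Sevoflurane (mean ± SD, n = 3 each), oligodendrocytes 14.6 ± 2.15% and 14.8 ± 3.18%, and microglia 3.41 ± 0.374% and 3.50 ± 0.248%. Choroid plexus epithelial cells, which secrete cerebrospinal fluid, were counted 65, 19 and 100 times in the Control libraries and 0, 1 and 4 times in the Sevoflurane libraries. Their share was 0.881 ± 0.603% and 0.0206 ± 0.0256%, a log2 fold change of -5.34 (SE 1.16) that missed the threshold (edgeR, BH-adjusted p = 0.0554; exact permutation p = 0.1). The 0 of 8996 cells in Sevoflurane 1 allows a share of up to 0.0333% from counting alone. Astrocytes made up 10.0 ± 0.440% and 7.73 ± 2.56% (log2 fold change -0.37, SE 0.29, edgeR BH-adjusted p = 0.704, exact permutation p = 0.1), with the lowest share, 4.77%, in Sevoflurane 1 and a log2 fold change of -0.12 without that library. Ependymal cells, fibroblasts, oligodendrocyte precursors, committed precursors, endothelial cells and pericytes had adjusted p of 0.686 to 0.955 in the same edgeR test. The choroid plexus share passed the threshold without Control 2 (edgeR, BH-adjusted p = 0.019), with doublets kept (0.030) and with DESeq2 (8.25e-05). It missed the threshold in the other edgeR settings, among them without Control 1 (0.192), Control 3 (0.211), Sevoflurane 1 (0.163) and Sevoflurane 2 (0.270). At clustering resolution 2 (0.0918) and with a class for each cell (0.124), no choroid plexus cell was counted in a Sevoflurane library, so no fold is given there.

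**Figure D1:**
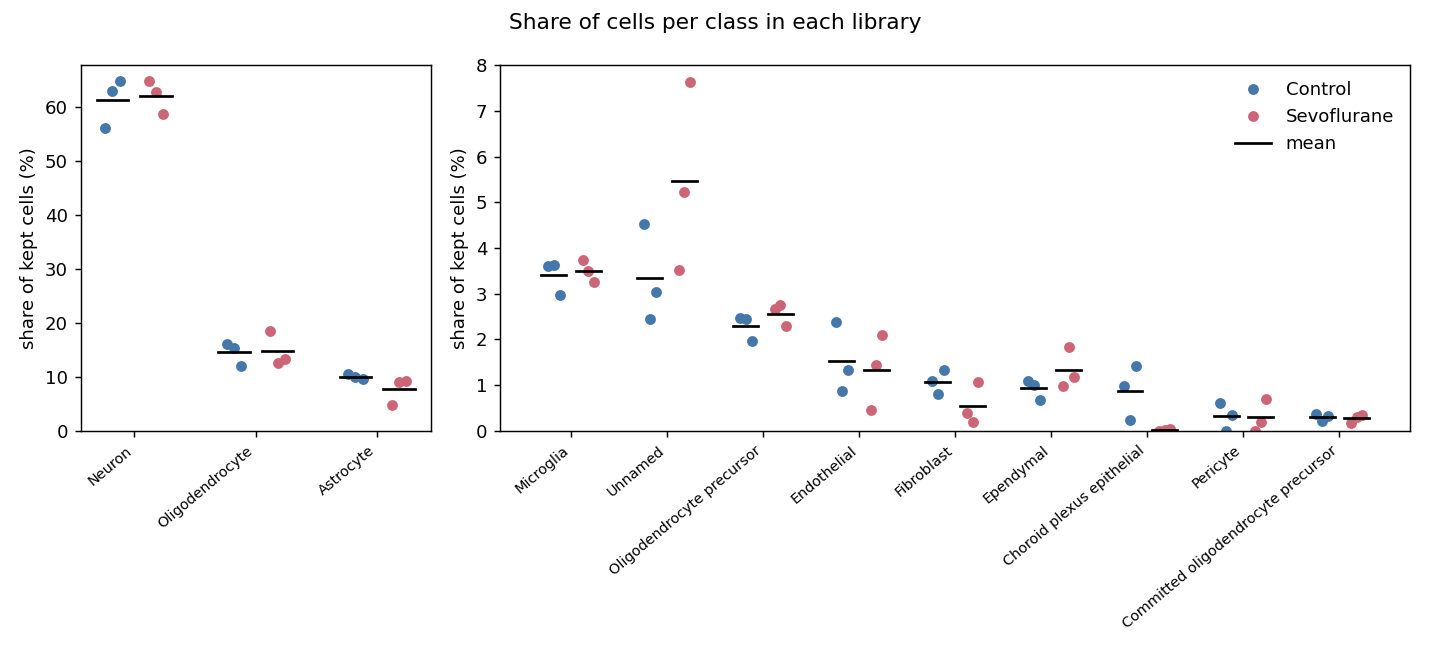
Share of kept cells (%) of each class in each of the 6 libraries, with Control and Sevoflurane libraries as points and the group mean as a bar. The choroid plexus epithelial share was 0.881% on average in Control and 0.0206% in Sevoflurane, and no class passed the threshold.

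The 3 unnamed clusters together held 3.34 ± 1.07% of the cells in Control and 5.46 ± 2.06% in Sevoflurane (exact permutation p = 0.2). Most of these cells lay in cluster 10, led by mitochondrially encoded genes, at 2.79 ± 1.03% and 4.75 ± 1.79%. Cluster 23, led by Bnc2 and Adamtsl3, held 0.547 ± 0.159% and 0.236 ± 0.341%. Cluster 31, led by the transcription factor genes Ebf2 and Zfhx3, held no cell of a Control library and 0.400%, 0.649% and 0.382% of the Sevoflurane libraries.

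Ttr, which encodes the thyroid hormone carrier transthyretin made by choroid plexus epithelium, fell in each of the 7 tested classes. In neurons it went from 147 ± 131 to 1.21 ± 0.218 CPM (n = 3 each, log2 fold change -6.93, SE 0.76, edgeR BH-adjusted p = 0.0114), and in microglia from 760 ± 687 to 4.5 ± 4.68 CPM (-7.26, SE 0.68, edgeR BH-adjusted p = 7.45e-06). The gene lies on chromosome 18 from 20665280 to 20674321 (GRCm38). Over the 7 tested classes, a cell of a Control library carried 1.38 to 1.54 Ttr UMIs on average, and a cell of a Sevoflurane library 0.00839 to 0.0339. The other classes were not measured for this. Depth was far less equal: in Control 1 the median was 9285 UMIs in neurons and 1956 in microglia. The Ttr folds of single classes are therefore not shown to be a change within those cells. Neuronal transcripts were also counted in glial cells: the 12 neuron markers had a median CPM in microglia of 1.03 times that in neurons. This ratio is in CPM and not in UMIs per cell, of which microglia had fewer. Free RNA was not removed, so calls and lists in glial classes may partly reflect neuronal RNA.

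Across the 7 classes, edgeR called 725 genes in neurons, 253 in astrocytes, 177 in endothelial cells, 80 in oligodendrocyte precursors, 59 in oligodendrocytes, 41 in ependymal cells and 31 in microglia. Genes that were lower with sevoflurane tended to be long: their median genomic span was 196.5 kb in neurons and 334.3 kb in oligodendrocyte precursors, against 37.56 and 12.89 kb for the higher genes and 23.06 and 35.43 kb over all genes tested in these classes. The rank correlation of span and log2 fold change across genes, which are not independent replicates, was -0.247 in neurons and between -0.085 and -0.343 in all 7 classes. When a smooth trend of each library with span was removed, an alternative chosen after the data had been seen, the split of calls in neurons went from 265 higher and 460 lower to 232 and 195, and that in oligodendrocyte precursors from 7 and 73 to 2 and 8.

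**Figure D2:**
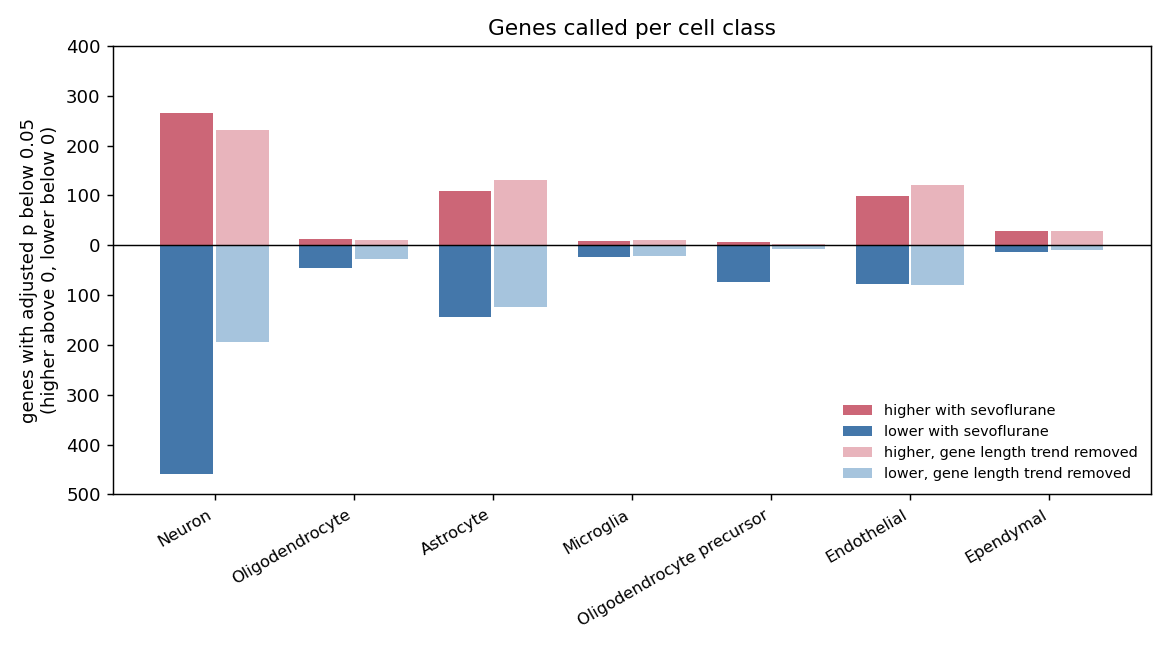
Number of genes with a BH-adjusted p below 0.05 in edgeR in each of the 7 classes, with genes higher with sevoflurane above 0 and lower below 0. Dark bars are the counts as tested and light bars those after removal of the trend with gene length, where neurons have 460 lower calls as tested and 195 after, 161 of them in both.

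In neurons, the largest falls after Ttr among called genes with a mean of at least 20 CPM were in Sav1, a scaffold of the Hippo pathway, in Chst9, a carbohydrate sulfotransferase, and in Cobl, an actin nucleator. Chst9 (ENSMUSG00000047161, chromosome 18 from 15451924 to 15760157) fell from 152 ± 15.3 to 73.0 ± 8.62 CPM (n = 3 each, log2 fold change -1.05, SE 0.10, edgeR BH-adjusted p = 0.00907). Lrrtm3, a synaptic adhesion protein gene (ENSMUSG00000042846, chromosome 10 from 63928472 to 64090277), fell from 287 ± 4.90 to 163 ± 9.20 CPM (-0.82, SE 0.06, edgeR BH-adjusted p = 0.00649). The log2 fold changes were -1.28 for Sav1, -1.03 for Cobl, -0.94 for Tmem44, -0.84 for Prr16, -0.83 for the sialyltransferase gene St3gal1, -0.81 for Cys1 and -0.81 for Adcy8, a calcium-stimulated adenylyl cyclase, with edgeR BH-adjusted p from 0.0114 to 0.0479. Among the genes that rose, Klhl10 (ENSMUSG00000001558, chromosome 11 from 100441917 to 100457022) went from 14.1 ± 0.756 to 24.1 ± 1.29 CPM (0.77, SE 0.08, edgeR BH-adjusted p = 0.00907). Tiparp, an ADP-ribosyltransferase gene induced by the aryl hydrocarbon receptor, rose by 0.94 (SE 0.14), the integrin gene Itga11 by 0.69 (SE 0.08) and Pcolce2 by 0.63 (SE 0.08), while Rgs9, Hfm1, Zdbf2 and Rccd1 rose by 0.70, 0.64, 0.57 and 0.54. The transcription factor gene Zfhx3 was higher by 1.07 (SE 0.15) and Pld5 by 0.67 (SE 0.13), but both differences were gone when the neuron clusters were taken in equal numbers (0.00 and -0.01). Without Sevoflurane 1, the genes Rgs9, Hfm1, Zdbf2, Cobl, Tmem44 and Cys1 were not called (edgeR BH-adjusted p = 0.0989, 0.0743, 0.0968, 0.0555, 0.0592 and 0.109). Leaving out a Control library ended more calls. Over all classes, with a named gene counted once for each class in which it was called, there were 117 calls. Of these, 54, 60 and 51 were lost without Control 1, 2 and 3, against 20 of 115 without Sevoflurane 1. Of the genes above, Tiparp, Pcolce2, Rgs9, Zdbf2, Rccd1, Cobl, Tmem44, Adcy8, Zfhx3 and Pld5 were not called without Control 1, nor without Control 2, nor without Control 3. Without neuron clusters 12 and 30, 14 of the 35 named genes of neurons lost the call and 2 changed sign.

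The neuronal test covered 18857 genes, of which 3910 had an unadjusted p under 0.05. All 725 called genes separated the 3 libraries of either group without overlap, as did 26.7% of all genes tested, where chance gives 10%. The count depended on every library: edgeR called 63 genes without Control 1, 46 without Control 2, 43 without Control 3, 358 without Sevoflurane 1, 218 without Sevoflurane 2 and 437 without Sevoflurane 3. It called 307 without neuron clusters 12 and 30, a setting chosen after the data had been seen, and DESeq2 called 1480.

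Of the fixed lists in neurons, the unfolded protein response, the chaperones and signals of endoplasmic reticulum stress, was lower as a list, and 7 of its 20 tested members fell. Hsp90b1 fell from 94.3 ± 5.25 to 65.5 ± 6.54 CPM (n = 3 each, log2 fold change -0.53, SE 0.08), and Pdia4, Xbp1 and Dnajc3 fell by 0.76, 0.55 and 0.42 on the log2 scale. The list passed camera (BH-adjusted p = 3.20e-05) and not with an estimated correlation (adjusted p = 0.848); adjusted over the list alone, 12 members fell. Of the 21 channel genes that anaesthetics act on, 4 fell, among them Gabrb2, Grin2b and Grin2a by 0.42, 0.26 and 0.32 (camera BH-adjusted p = 0.00514, adjusted p = 0.848 with an estimated correlation), and adjusted over the list alone 6 fell and 2 rose. Gabrb2 encodes a subunit of the GABA-A receptor, and Grin2a and Grin2b encode subunits of the NMDA receptor. Of the 20 synaptic genes, 3 fell, among them Syt1 and Pclo by 0.37 and 0.26 (camera BH-adjusted p = 0.0164, adjusted p = 0.848 with an estimated correlation), and 9 fell adjusted over the list alone. Neuron markers passed as a lower list too (camera BH-adjusted p = 0.0487, adjusted p = 0.848 with an estimated correlation), with Syt1, Grin2b and Celf4 called, and with 5 lower and 1 higher adjusted over the list alone. After removal of the length trend the channel, synaptic and neuron marker lists no longer passed (camera BH-adjusted p = 0.498, 0.781 and 0.275), while the unfolded protein response did (4.35e-06). Hsp90b1, Pdia4, Xbp1, Dnajc3, Gabrb2, Grin2b, Grin2a, Pclo and Celf4 were each not called when any of the Control libraries was left out.

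Ribosomal protein genes were higher as a list in neurons with none of the 50 members called over all genes or adjusted over the list alone (median log2 fold change 0.28, camera BH-adjusted p = 7.88e-06, adjusted p = 0.855 with an estimated correlation). Immediate-early genes, the transcripts that respond first to stimulation, passed as a higher list with Maff called of 23 members, and 5 higher adjusted over the list alone (camera BH-adjusted p = 0.00583, adjusted p = 0.848 with an estimated correlation). Fosb and Fos had log2 fold changes of 1.23 (SE 0.32) and 1.16 (SE 0.31) without being called, and Maff was not called without Sevoflurane 1 (edgeR BH-adjusted p = 0.0892). In the list of glucocorticoid-responsive genes, Cdkn1a rose by 1.03 and Zbtb16 fell by 0.36 among 20 members, and 5 were higher and 1 lower adjusted over the list alone (camera BH-adjusted p = 0.0339, adjusted p = 0.848 with an estimated correlation). Nuclear genes of oxidative phosphorylation passed with none of 35 called by either count (camera BH-adjusted p = 0.0339, adjusted p = 0.902 with an estimated correlation), as did the 7 ependymal markers (0.0374, adjusted p = 0.848 with an estimated correlation). Choroid plexus markers passed as a lower list, with Ttr called of 10 members and 3 lower adjusted over the list alone (camera BH-adjusted p = 0.0308, adjusted p = 0.848 with an estimated correlation). After removal of the length trend, the glucocorticoid, oxidative phosphorylation, ependymal and choroid plexus lists no longer passed (camera BH-adjusted p = 0.0757, 0.252, 0.0757 and 0.0528), while ribosomal proteins and immediate-early genes did (1.05e-04 and 0.0398). Maff, Cdkn1a and Zbtb16 were each not called when any of the Control libraries was left out.

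In astrocytes, genes of the cholesterol synthesis list rose together. Of the 21 members of the list, 15 rose over all genes and 18 adjusted over the list alone, none fell, and the median log2 fold change was 1.19. Insig1, a sterol-sensing regulator (ENSMUSG00000045294, chromosome 5 from 28071363 to 28078662), rose from 33.8 ± 3.49 to 92.6 ± 20.2 CPM (n = 3 each, log2 fold change 1.44, SE 0.18, edgeR BH-adjusted p = 5.91e-04). Mvd, a mevalonate pathway enzyme (ENSMUSG00000006517, chromosome 8 from 122433601 to 122443422), rose from 10.7 ± 2.35 to 42.8 ± 9.67 CPM (2.01, SE 0.23, edgeR BH-adjusted p = 4.15e-04), Hsd17b7 by 1.41 (SE 0.20), and Cyp51 and Fdft1 each by 1.20 (SE 0.13). The list passed camera (BH-adjusted p = 6.81e-25) and the self-contained test fry (0.0124), and did not pass with an estimated correlation (adjusted p = 0.439). Aacs, an acetoacetyl-CoA synthetase gene outside the list that feeds the same pathway, rose by 1.42 (SE 0.15).

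**Figure D3:**
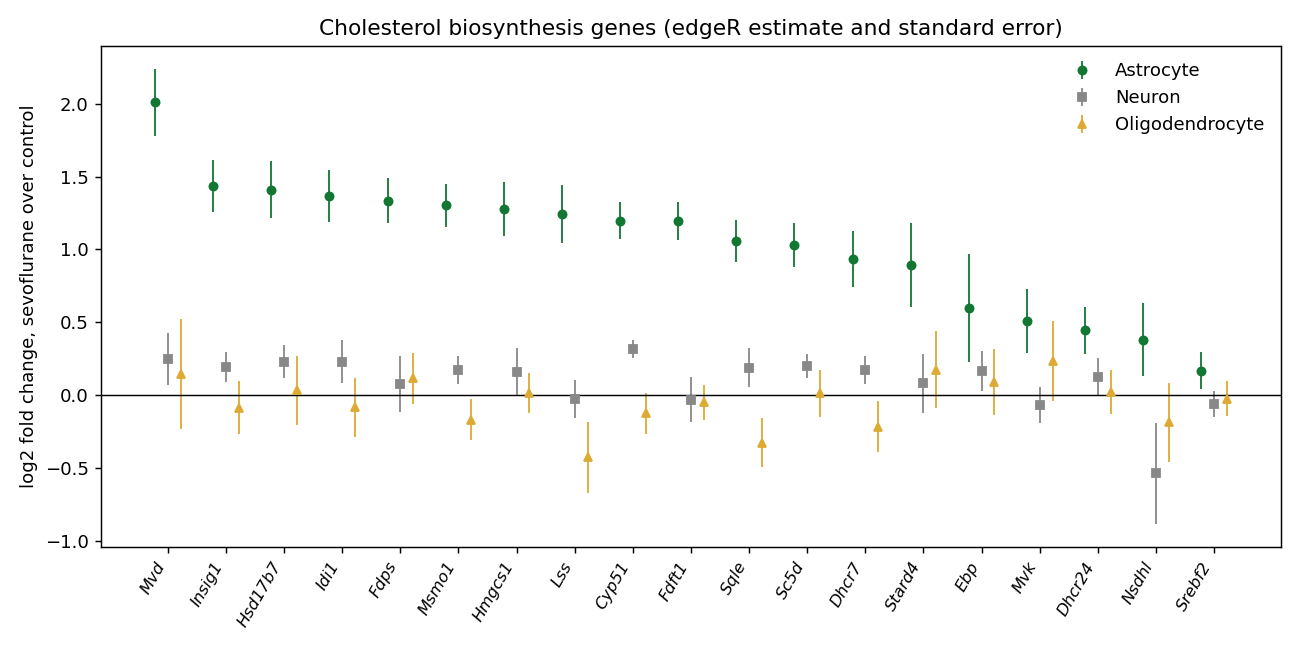
Log2 fold change (sevoflurane over control, edgeR) of genes of the cholesterol synthesis list in astrocytes, neurons and oligodendrocytes, with the standard error as a bar. The full list has a median of 1.19 in astrocytes, and Mvd stands at 2.01 in astrocytes, 0.25 in neurons and 0.14 in oligodendrocytes.

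Glucocorticoid-responsive genes were also higher in astrocytes, with 6 of 20 members risen over all genes and 12 adjusted over the list alone (camera BH-adjusted p = 5.26e-09, adjusted p = 0.595 with an estimated correlation). Pdk4, a kinase that limits the entry of pyruvate into the citric acid cycle, rose from 25.9 ± 0.941 to 67.5 ± 7.21 CPM (log2 fold change 1.39, SE 0.15), and Map3k6, Arl4d and Ddit4 rose by 2.34, 1.86 and 1.07. Other risen genes were Setdb2, a histone methyltransferase gene (2.09), the transporter gene Slc16a9 (1.71), Ccn1 (1.70), Arrdc2 (1.67), Plpp4 (1.5) and Anxa2 (1.45), with edgeR BH-adjusted p of 0.00234 to 0.0173. Grm3, the main metabotropic glutamate receptor gene of astrocytes (ENSMUSG00000003974, chromosome 5 from 9485541 to 9725170), fell from 1100 ± 320 to 338 ± 92.1 CPM (-1.72, SE 0.21, edgeR BH-adjusted p = 5.75e-04). Mgll, whose enzyme degrades endocannabinoids (ENSMUSG00000033174, chromosome 6 from 88724412 to 88828360), fell from 518 ± 66.3 to 228 ± 45.4 CPM (-1.17, SE 0.15, edgeR BH-adjusted p = 0.00109). Adcy8 fell by 1.26, the Notch target Hes5 by 1.25, Zbtb40 by 1.59, Shc3 by 1.23, Igfbp2 by 1.22 and Arhgef19 by 1.20 on the log2 scale. Ribosomal protein genes passed as a higher list with none of 50 called by either count (camera BH-adjusted p = 1.17e-07, adjusted p = 0.869 with an estimated correlation). So did immediate-early genes, with none of 15 called and 3 higher adjusted over the list alone (0.0116, adjusted p = 0.869 with an estimated correlation), and oxidative phosphorylation, with none of 35 called by either count (0.0185, adjusted p = 0.900 with an estimated correlation, and camera BH-adjusted p = 0.105 after removal of the length trend). Slc16a9 and Arhgef19 were each not called when any of the Control libraries was left out. In total, 109 of 12325 genes rose and 144 fell, and all 253 separated the groups without overlap, as did 19.9% of all genes tested, where chance gives 10%. EdgeR called 151 genes without Control 1, 56 without Control 2, 103 without Control 3, 390 without Sevoflurane 1 and 116 without Sevoflurane 2.

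In endothelial cells, genes of the immediate-early response rose, and so did a pair of genes of the ADAMTS family of secreted metalloproteases. Adamts9 (ENSMUSG00000030022, chromosome 6 from 92772699 to 92943492), rose from 31.5 ± 9.40 to 302 ± 199 CPM (n = 3 each, log2 fold change 3.19, SE 0.40, edgeR BH-adjusted p = 6.35e-04), and its relative Adamts1 from 34.7 ± 11.6 to 186 ± 46.1 CPM (2.43, SE 0.29, edgeR BH-adjusted p = 5.13e-04). Tnfrsf12a, the TWEAK receptor gene, rose by 2.72, the urokinase receptor gene Plaur by 2.66, Akap12 by 2.17, Nr4a3 by 2.08, the intermediate filament gene Nes by 2.05 and Pxdc1 by 2.02. Of 16 tested immediate-early genes, 5 rose over all genes and 8 adjusted over the list alone, among them Maff (2.31), Nr4a1 (2.05), Klf4 (1.57) and Klf6 (0.85) (camera BH-adjusted p = 5.77e-08, adjusted p = 0.619 with an estimated correlation). Of 18 glucocorticoid-responsive genes, Cdkn1a, Mt2, Sgk1 and Mt1 rose by 1.51, 1.28, 1.21 and 1.06, and the same number was called adjusted over the list alone (camera BH-adjusted p = 0.00258, adjusted p = 0.619 with an estimated correlation). St8sia4, a polysialyltransferase gene (ENSMUSG00000040710, chromosome 1 from 95587682 to 95667571), fell from 331 ± 84.3 to 72.7 ± 19.3 CPM (-2.24, SE 0.25, edgeR BH-adjusted p = 5.13e-04), Ankrd37 by 3.06, the growth factor gene Bmp6 by 2.47, and Zfp521, Vsir, Tril and Stxbp4 by 1.90, 1.86, 1.85 and 1.83. The interferon-induced genes Iigp1 and Ifit1 fell by 2.40 and 1.94. Without Sevoflurane 1, Klf6 was not called (edgeR BH-adjusted p = 0.0839), nor was it without Control 1, 2 or 3. Without Control 1, the calls of Akap12, Nr4a3, Pxdc1, Ifit1, Zfp521, Vsir, Stxbp4, Klf4, Mt2, Sgk1 and Mt1 were lost as well.

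Interferon response genes passed as a lower list in endothelial cells, with Ifit1 called of 12 and 2 lower adjusted over the list alone (camera BH-adjusted p = 0.00585, adjusted p = 0.619 with an estimated correlation). Cholesterol synthesis passed as a higher list with none of 12 called over all genes and 1 adjusted over the list alone (camera BH-adjusted p = 0.0268, adjusted p = 0.619 with an estimated correlation). Smooth muscle markers passed as a lower list with none of 6 called and 3 lower adjusted over the list alone (camera BH-adjusted p = 0.0268, adjusted p = 0.619 with an estimated correlation); Acta2 stood at 108 ± 127 and 27.4 ± 20.4 CPM and Tagln at 81.0 ± 77.6 and 23.5 ± 20.7 CPM. The log2 fold changes of Acta2 and Myl9 were -1.82 and -0.49, and turned to 1.38 and 0.35 with equal cell numbers; that of Acta2 was -0.06 without Control 1. The 21 genes of the blood-brain barrier did not pass (0.187). With the length trend removed, synaptic genes and neuron markers passed as higher lists in endothelial cells (camera BH-adjusted p = 0.036 and 0.0399, against 0.123 and 0.116 before). The unfolded protein response and ribosomal proteins then passed as lower lists (0.036 each, against 0.0653 and 0.216 before). Of 7814 genes, 99 rose and 78 fell, and 176 of the 177 separated the groups without overlap, as did 18.7% of all genes tested, where chance gives 10%. This class had 42 cells in Sevoflurane 1 and 170 in Sevoflurane 3. EdgeR called 47 genes without Control 1, 75 without Control 3, 68 without Sevoflurane 2 and 144 without Sevoflurane 1.

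In oligodendrocytes, the myelinating cells, 13 genes rose and 46 fell among 12441. Adam11, a catalytically inactive metalloprotease family gene (ENSMUSG00000020926, chromosome 11 from 102761439 to 102780262), fell from 147 ± 31 to 37.2 ± 6.21 CPM (n = 3 each, log2 fold change -2.0, SE 0.17, edgeR BH-adjusted p = 6.57e-04), and Sav1 fell by 1.5 (SE 0.21) and Ttr by 6.44 (SE 0.64). The adaptor gene Sh2b2 rose from 5.71 ± 2.85 to 56.9 ± 32.1 CPM (3.36, SE 0.48, edgeR BH-adjusted p = 0.018), St8sia3os by 2.18 (SE 0.33) and the mitochondrial folate enzyme gene Mthfd1l by 1.21 (SE 0.19); these 3 were each not called when any of the Control libraries was left out. The unfolded protein response was lower as a list with none of 18 members called over all genes and 7 adjusted over the list alone (camera BH-adjusted p = 1.07e-04, adjusted p = 0.886 with an estimated correlation), where Pdia6 and Hspa5 had log2 fold changes of -0.68 and -0.55. Myelin genes passed as a lower list with none of 21 called over all genes and 1 adjusted over the list alone (camera BH-adjusted p = 0.0399, adjusted p = 0.886 with an estimated correlation). Car2, a carbonic anhydrase gene, stood at 656 ± 30.4 and 435 ± 66.2 CPM (-0.59, SE 0.13, edgeR BH-adjusted p = 0.0713).

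Higher lists in oligodendrocytes, all with an adjusted p of 0.886 with an estimated correlation, were ribosomal proteins (camera BH-adjusted p = 2.28e-10), oxidative phosphorylation (1.07e-04), glucocorticoid response (2.26e-04) and the mitochondrially encoded genes (0.00129). None of their 50, 35, 19 and 13 members was called over all genes, and adjusted over the list alone 6 higher and 1 lower were called in the glucocorticoid list and none in the other 3. With the length trend removed, the mitochondrially encoded list no longer passed (camera BH-adjusted p = 0.269). Synaptic genes and neuron markers then passed as higher lists (0.0249 each, median log2 fold change 0.16 and 0.17, against 0.695 and 0.210 before). Choroid plexus markers passed as a lower list with Ttr called of 5 and 2 lower adjusted over the list alone (0.00129, adjusted p = 0.886 with an estimated correlation). All 59 called genes separated the groups without overlap, as did 18.5% of all genes tested, where chance gives 10%. EdgeR called 5 genes without Control 1, 6 without Control 2, 13 without Control 3, 22 without Sevoflurane 2 and 85 without Sevoflurane 1, and the median span of the lower genes was 90.13 kb.

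In oligodendrocyte precursors, 7 genes rose and 73 fell among 9395. Dbi, which encodes the diazepam-binding inhibitor, rose from 88.4 ± 8.34 to 148 ± 17.1 CPM (n = 3 each, log2 fold change 0.74, SE 0.16, edgeR BH-adjusted p = 0.0278), Gpatch4 by 1.53 (SE 0.31) and the soluble adenylyl cyclase gene Adcy10 by 1.93 (SE 0.46). Ttr fell by 6.99, the dynein heavy chain gene Dnah2 by 1.33 (SE 0.31) and Sav1 by 1.31 (SE 0.32). Without Sevoflurane 1, Adcy10, Dnah2 and Sav1 were not called (edgeR BH-adjusted p = 0.229, 0.107 and 0.0591), and Adcy10, Dbi, Rpl23 and Pdia3 were each not called when any of the Control libraries was left out. Cholesterol synthesis passed as a higher list with none of 15 called over all genes and 2 adjusted over the list alone (camera BH-adjusted p = 5.14e-05, adjusted p = 0.591 with an estimated correlation), where Cyp51 had a log2 fold change of 0.96 (SE 0.27). Ribosomal proteins passed as a higher list, with Rpl23 risen by 0.76 over all genes and 10 of 50 adjusted over the list alone (camera BH-adjusted p = 4.44e-09, adjusted p = 0.591 with an estimated correlation). Oxidative phosphorylation passed with none of 35 called by either count (camera BH-adjusted p = 0.00130, adjusted p = 0.591 with an estimated correlation, and 0.204 by camera after removal of the length trend), and oligodendrocyte markers with none of 8 called over all genes and 1 adjusted over the list alone (0.0340, adjusted p = 0.591 with an estimated correlation). The unfolded protein response passed as a lower list, with Pdia3 fallen by 0.84 of 15 members, and 3 lower and 1 higher adjusted over the list alone (camera BH-adjusted p = 0.0423, adjusted p = 0.591 with an estimated correlation). Of the 80 called genes 79 separated the groups without overlap, as did 16.2% of all genes tested, where chance gives 10%. EdgeR called 32 genes without Control 1, 3 without Control 2, 28 without Control 3, 65 without Sevoflurane 1 and 23 without Sevoflurane 2.

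In microglia, the resident macrophages of the brain, 8 genes rose and 23 fell among 9250. F13a1, the gene of a coagulation factor subunit and a marker of border-associated macrophages in the fixed list, fell from 294 ± 93.2 to 38.9 ± 47.5 CPM (n = 3 each, log2 fold change -2.93, SE 0.43, edgeR BH-adjusted p = 0.00189), Slfn9 by 3.34 (SE 0.58) and Ttr by 7.26. Border-associated macrophages named no cluster, so their share within this class was not measured. The fall of F13a1 is therefore not shown to be a change within microglia. Fggy, a carbohydrate kinase gene, rose by 1.91 (SE 0.33), the inflammasome sensor gene Nlrp1b by 1.52 (SE 0.33) and Cdkl3 by 1.26 (SE 0.27), with edgeR BH-adjusted p of 0.00949 to 0.0415. Without Sevoflurane 1, Nlrp1b and Cdkl3 were not called (edgeR BH-adjusted p = 0.0821 and 0.121), nor was either when any of the Control libraries was left out. Higher lists were ribosomal proteins (camera BH-adjusted p = 2.39e-05), oxidative phosphorylation (0.00474) and glucocorticoid response (0.0215), each with an adjusted p of 0.914 with an estimated correlation. None of their 50, 35 and 15 members was called over all genes, and adjusted over the list alone 1 was higher, in the glucocorticoid list. After removal of the length trend none of these 3 lists passed (camera BH-adjusted p = 0.147, 0.174 and 0.104). Neuron markers then passed as a higher list (0.0448, median log2 fold change 0.23, against 0.147 and 0.13 before) and the unfolded protein response as a lower list (0.0443, against 0.147 before). Without Control 2 or without Sevoflurane 2, camera called 0 lists in microglia. The complement list had its smallest BH-adjusted p by camera here (0.389), and did not pass in any of the 3 classes where it was tested. The homeostatic microglia list had its smallest in astrocytes (0.0508), and passed there as a lower list after removal of the length trend (camera BH-adjusted p = 0.0426, median log2 fold change -0.21). All 31 called genes separated the groups without overlap, as did 13.8% of all genes tested, where chance gives 10%. EdgeR called 17 genes without Control 1, 10 without Control 2, 11 without Control 3, 43 without Sevoflurane 1 and 20 without Sevoflurane 2.

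In ependymal cells, which line the ventricles, 28 genes rose and 13 fell among 7230. Nr4a3, an immediate-early nuclear receptor gene (ENSMUSG00000028341, chromosome 4 from 48045153 to 48086447), rose from 29.1 ± 11.9 to 318 ± 130 CPM (n = 3 each, log2 fold change 3.35, SE 0.33, edgeR BH-adjusted p = 1.07e-06). Of 10 immediate-early genes of the fixed list, Fos, Nr4a1, Dusp1 and Egr1 rose by 2.95, 2.59, 2.30 and 1.69, and 6 rose adjusted over the list alone (camera BH-adjusted p = 1.67e-05, adjusted p = 0.438 with an estimated correlation). Fos and Nr4a1 were not tested without Sevoflurane 1, and Dusp1 was not called then (edgeR BH-adjusted p = 0.0834). These 3 were not called without Control 1 or without Control 2. Ahsa2, a chaperone activator gene, fell by 1.98 (SE 0.36), Rgs20 by 1.63 (SE 0.33) and Ttr by 5.21 (SE 0.53). Higher lists without a member called over all genes were ribosomal proteins (50 members, camera BH-adjusted p = 1.29e-04), oxidative phosphorylation (32 members, 0.00125) and lysosome and autophagy (21 members, 0.0194). Their adjusted p with an estimated correlation was 0.827, 0.827 and 0.438, and adjusted over the list alone 1 lysosomal gene was called. After removal of the length trend, none of these 3 lists passed (camera BH-adjusted p = 0.111, 0.0708 and 0.0708). All 41 called genes separated the groups without overlap, as did 14.9% of all genes tested, where chance gives 10%. EdgeR called 18 genes without Control 1, 15 without Control 2 and 74 without Sevoflurane 1.

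The difference of the effect between classes was tested directly in edgeR for 3 pairs of classes. It was unequal in astrocytes and neurons for 354 of 18569 genes, 213 of them more positive in astrocytes, in astrocytes and oligodendrocytes for 130 of 13366 genes, and in oligodendrocytes and neurons for 97 of 18162 genes. The first count was 185 without Control 2 and 612 without Sevoflurane 1, the next 77 without Control 3, 65 without Sevoflurane 2 and 59 without Sevoflurane 3, and the last 56 without Control 3, 60 without Sevoflurane 2 and 58 without Sevoflurane 3. Of the cholesterol list, 16 of 21 genes had a more positive effect in astrocytes than in neurons, and 15 of 21 a more positive effect than in oligodendrocytes. Mvd differed by 1.75 between astrocytes and neurons (edgeR BH-adjusted p = 1.38e-04). Of the glucocorticoid-responsive list, 4 of 20 had a more positive effect in astrocytes than in neurons. The unfolded protein response list had 1 of 19 members with a more positive effect in astrocytes than in neurons and 0 of 19 unequal between oligodendrocytes and neurons.

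Many fixed lists passed in no class by camera as tested. Not every list was tested in all 7 classes. The smallest BH-adjusted p over the classes where a list was tested was 0.0527 for disease-associated microglia (in oligodendrocyte precursors), 0.0613 for heat shock, 0.0653 for NF-kB targets, 0.0870 for NRF2 and antioxidant genes, and 0.0884 for MHC class I, p53 and apoptosis and A1 astrocyte genes. It was 0.116 for the circadian clock, 0.138 for glycolysis and Alzheimer risk genes, 0.175 for hypoxia and 0.2 for ferroptosis and iron. It was 0.352 for the m6A machinery, 0.355 for A2 astrocyte genes and endothelial activation, 0.382 for the inflammasome, 0.515 for disease-associated oligodendrocyte genes, 0.531 for the cell cycle, 0.549 for pan-reactive astrocyte genes (in neurons) and 0.889 for MHC class II. The A2 astrocyte and MHC class II lists were tested in neurons alone, so not in astrocytes or microglia. Endothelial activation was tested in neurons and oligodendrocytes, and not in endothelial cells. The inflammasome list was tested in 2 classes, and the cell cycle and pan-reactive astrocyte lists in 3 each. Among markers of cell types, microglia (0.0556), neuroblasts (0.0583), oligodendrocyte precursors (0.0612) and astrocytes (0.0653) came nearest to the threshold. With the length trend removed, microglia markers passed as a lower list in astrocytes (0.0426) and precursor markers as a lower list in oligodendrocyte precursors (0.0348). Committed precursors (0.347), pericytes (0.185), endothelial cells (0.576), fibroblasts (0.876) and erythroid cells (0.891) lay further away. Of these, the markers of committed precursors, fibroblasts and erythroid cells were tested in neurons alone. The sex-linked list, tested in neurons alone, had 0.710. Sevoflurane 1 alone stood apart in these genes, which widens the spread within its group. This value therefore does not show that sex had no bearing on the comparison. Cytokines and chemokines and the markers of border-associated macrophages, T or NK cells, B cells, neutrophils, and monocytes or dendritic cells had fewer than 5 tested members in every class.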

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

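The tests on Ttr, on the tissue piece and on genes shared by classes were chosen after their results had been seen, as were the removal of the length trend as an alternative and the count of splits for called genes.

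Genes with an unequal effect in 2 classes, by the edgeR interaction test, numbered 354 for astrocytes and neurons, 130 for astrocytes and oligodendrocytes, and 97 for oligodendrocytes and neurons. A design of 3 against 3 libraries makes 10 splits and cannot give a share under 0.05: the highest count in another split was 1, 2 and 3 for these pairs, and 1 split, the real one, reached the real count in each.

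For named genes, the log2 fold change in astrocytes minus that in neurons was 2.30 for Map3k6, 1.87 for Plpp4, 1.85 for Setdb2, 1.78 for Slc16a9, 1.46 for Arrdc2, 1.19 for Pdk4, and 0.53 for Zbtb16. Among the sterol genes it was 1.75 for Mvd, 1.48 for Aacs, 1.23 for Insig1, 1.22 for Fdft1, 1.19 for Hsd17b7 and 0.89 for Cyp51. Genes that fell in neurons had a difference of 1.25 for Sav1, 0.96 for Chst9 and 0.79 for Lrrtm3. It was negative for Grm3 (-1.26), Mgll (-1.03), Tiparp (-0.84) and Shc3 (-0.81).

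The difference of astrocytes minus oligodendrocytes was 2.28 for Adam11, 1.87 for Mvd, 1.58 for Insig1, 1.48 for Sav1, 1.43 for Hsd17b7, 1.36 for Cyp51, 1.28 for Aacs, 1.27 for Fdft1 and 1.24 for Arrdc2. It was -3.81 for Sh2b2, -1.28 for Mgll and -1.07 for Grm3. Oligodendrocytes minus neurons gave 3.50 for Sh2b2, 2.08 for St8sia3os, 1.77 for St3gal1, 1.08 for Mthfd1l, 0.85 for Lrrtm3, -1.56 for Zfhx3 and -2.01 for Adam11.

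Choroid plexus cells and Ttr were lower with sevoflurane, while neuron cluster 30 and the unnamed cluster 31, at 0.477% of the cells with sevoflurane and with no cell in Control, were larger. In Control libraries the mean Ttr UMIs per cell of the highest of the 7 tested classes were 1.116 times those of the lowest. Such near-equal counts in classes of unlike depth argue against Ttr made by the cells of these classes. Free RNA of choroid plexus cells may carry the fall of Ttr into them. That test was first made on CPM, where the ratio of 5.17 decided nothing, and was changed to UMIs per cell, since free RNA adds UMIs per droplet whatever the size of the cell. Another piece of tissue in the sevoflurane animals cannot be told apart from the treatment, because the labels name no piece; the share of cluster 30 (exact permutation p = 0.1, the smallest possible) is part of the pattern and decides nothing. A treatment effect on these populations stays open too.

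Of 1210 genes called in any class, 113 were called the same way in at least 2 classes, 22 higher and 91 lower, and 14 in opposite directions in 2 classes. The pattern was first set at 4 or more classes, which gave 4 genes, and was then widened. Of 111 autosomal genes, 13 had another within 1 Mb, against a median of 18 in 10000 random draws of as many genes. Neighbours were thus not frequent over the genes as a whole. A total of this kind cannot exclude a single genome region that differs between the animals, so that stays open. Free RNA of neurons may contribute, with a median microglia-to-neuron level in CPM of 0.4893 over these genes and up to 3.266 for neuron markers, a bound easily met. A trend with gene length may contribute too: after its removal 46 of the 113 were still called in at least 2 classes. What the treatment does to these genes in each class was not separated from any of these.

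Lower calls had a longer median span than higher calls in each of the 7 classes, although higher calls too were longer than all genes tested in 6, and the ribosomal protein list passed camera as higher in 6 classes with the preset correlation and in none with an estimated correlation (adjusted p of 0.591 to 0.914). For the lower calls of neurons, a length trend of each library may account for part: 195 lower genes were called after its removal, 161 of them among the 460 called before. For ribosomal proteins, the list still passed camera as higher at the preset correlation after the removal in neurons, oligodendrocytes, astrocytes and precursors. This does not decide whether the trend is the whole cause there. Before the removal, 4, 4, 4 and 3 of the 10 splits in these classes, the real one included, gave a camera p at least as small as the real one. In microglia and ependymal cells the list then missed the threshold (camera BH-adjusted p = 0.147 and 0.111). Its median log2 fold changes there were 0.11 and 0.09, beside 0.11 in precursors, where it passed. In endothelial cells it passed as lower (median log2 fold change -0.12, camera BH-adjusted p = 0.036). The trend itself may be technical or an effect of the treatment, and other splits of the libraries gave a rank correlation of span and log2 fold change of -0.344 to 0.244 in neurons against -0.247 for the real split.

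For the counts of called genes, 1 of the 10 splits, the real one, reached the real count in every class, and 10 splits cannot give a share under 0.05. The real counts and the highest of the other splits were 725 and 1 in neurons, 59 and 3 in oligodendrocytes, 253 and 1 in astrocytes, 31 and 4 in microglia, 80 and 4 in oligodendrocyte precursors, 177 and 0 in endothelial cells, and 41 and 2 in ependymal cells. The lists called by camera were not as rare: with real counts of 10, 7, 5, 3, 5, 5 and 4 lists in the same order of classes, 5, 5, 8, 9, 6, 6 and 4 of the 10 splits gave at least as many, and the highest of the other splits gave 12, 12, 11, 17, 9, 11 and 8. By unadjusted camera p, the real split had the smallest value for cholesterol synthesis in astrocytes (1.89e-26, against 6.76e-08 as the smallest of the other splits), in precursors and in endothelial cells. The same was so for immediate-early genes in endothelial (1.7e-09 against 3.38e-06) and ependymal cells (5.77e-07 against 0.00728), and for the unfolded protein response (6.37e-06 against 3.36e-04) and choroid plexus markers in oligodendrocytes. It was so too for glucocorticoid response in astrocytes, channels and neuron markers in neurons, and lysosome and autophagy in ependymal cells. For the other called lists another split had a smaller p: in neurons it gave 5.19e-36 against 1.58e-07 for ribosomal proteins, 1.06e-06 against 1.28e-06 for the unfolded protein response and 1.36e-08 against 4.67e-04 for immediate-early genes.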

How the results depend on the processing

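The settings chosen after the data had been seen were the removal of the length trend, neuron clusters in equal numbers, and neurons without clusters 12 and 30.

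A named gene was counted once for each class in which it was called, so that Ttr counted 7 times. Of these 117 calls, 117 were kept in the same direction with RLE factors and with no filter. The number kept was 116 with stricter cells, 103 with doublets kept, 96 with the length trend removed, and 63, 57 and 66 without Control 1, 2 and 3. Of those tested, it was 95 of 115, 77 of 115 and 93 of 116 without Sevoflurane 1, 2 and 3, 114 of 116 at resolution 2, 97 of 100 with DESeq2, 94 of 110 with a class for each cell and 92 of 104 with equal cell numbers. In neurons, 25 of 35 were still called with the clusters in equal numbers (8 lost the call and 2 changed sign) and 19 of 35 without clusters 12 and 30 (14 and 2). Over all settings and all pairs of a named gene and a class, 3281 values were unchanged in call and direction, 368 lost the call, 71 gained it and 11 changed sign. Among genes with a mean count of at least 20, edgeR recovered 58% of those with a simulated fold of 2 in ependymal cells and 80% in astrocytes. A gene not called is therefore not shown to be unchanged. Where no cause is named, the cause was not tested.

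With DESeq2, called genes numbered 1480 in neurons, 147 in oligodendrocytes, 149 in oligodendrocyte precursors and 24 in ependymal cells, and the choroid plexus share had a log2 fold change of -5.44. With no filter on low counts, they numbered 512 in oligodendrocytes, 606 in astrocytes, 112 in microglia, 162 in precursors, 385 in endothelial cells and 89 in ependymal cells, and genes of unequal effect 307 for oligodendrocytes and neurons, 551 for astrocytes and neurons, and 311 for astrocytes and oligodendrocytes. A class for each cell gave 99 genes in astrocytes, 48 in precursors and 24 in ependymal cells, turned the share of committed precursors to 0.07, of microglia to -0.21 and of oligodendrocytes to -0.03, none of them called, and Mbp in precursors to -0.21. With doublets kept, precursors had 52 genes, the choroid plexus share was -3.57, and 8 lists passed in astrocytes and 2 in ependymal cells. Equal cell numbers gave 47 genes in precursors, 112 in endothelial and 19 in ependymal cells, and turned Acta2 (1.38) and Myl9 (0.35) in endothelial cells and Rps3 (-0.15) in ependymal cells.

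Camera with an estimated correlation called 0 lists in each of the 7 classes, where the preset correlation called 3 to 10, and fry called 0 except 3 in astrocytes. Removal of the length trend gave 427 genes in neurons, 39 in oligodendrocytes and 10 in precursors, 3 lists in neurons, 9 in endothelial and 1 in ependymal cells, and turned Dlg2 in neurons to 0.12. Equal numbers of the neuron clusters gave Zfhx3 0.00, Pld5 -0.01 and Clic6 -0.80. Without clusters 12 and 30, neurons had 307 genes, with Zfhx3 at -0.01, Pld5 at -0.04 and Clic6 at -0.92; Zfhx3 and Pld5 were among the leading genes of cluster 30.

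The replicate numbers did not pair the libraries: deviations of libraries with the same number correlated at -0.192 to 0.026 over the 7 classes. With the replicate block, 86 of the 117 calls of named genes were kept, and the choroid plexus share had an edgeR BH-adjusted p of 0.154. In that setting, 134 genes were called in neurons, 28 in oligodendrocytes, 10 in precursors and 110 in endothelial cells, 8 lists passed in astrocytes, and the pericyte share was 0.30. Neuron clusters 13, 17, 18, 19, 20, 21 and 22 then had 1, 48, 66, 46, 30, 12 and 110 called genes.

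With 1 library left out in turn, called genes ranged from 43 to 437 in neurons, 5 to 85 in oligodendrocytes, 56 to 390 in astrocytes, 10 to 46 in microglia, 3 to 94 in precursors, 47 to 180 in endothelial and 15 to 74 in ependymal cells. Lists ranged from 5 to 10 in neurons, 4 to 10 in astrocytes, 0 to 6 in microglia, 2 to 10 in endothelial and 2 to 9 in ependymal cells. Genes of unequal effect ranged from 185 to 612 for astrocytes and neurons, 59 to 143 for astrocytes and oligodendrocytes, and 56 to 132 for oligodendrocytes and neurons. The log2 fold change of shares ranged from -6.87 to -4.76 for choroid plexus, -0.52 to -0.12 for astrocytes, -1.86 to -0.57 for fibroblasts, 0.23 to 0.71 for ependymal cells, 0.06 to 0.23 for precursors, -0.37 to 0.12 for committed precursors, -0.67 to 0.28 for endothelial cells, -0.05 to 0.09 for microglia, -0.04 to 0.06 for neurons, -0.17 to 0.13 for oligodendrocytes and -1.68 to 0.80 for pericytes.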

Other observations

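All tests of neuron clusters were chosen after the data had been seen, and their gene counts were split afterwards too. The clusters were made from the same 6 libraries without integration, and the p-values of their shares do not take this into account.

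Neuron cluster 30, whose leading genes were Pld5 and Zfhx3, held 0.127 ± 0.110% of the neurons in Control and 3.28 ± 0.808% with sevoflurane (n = 3 each, log2 fold change 4.72, SE 0.547, edgeR BH-adjusted p = 4.39e-04, exact permutation p = 0.1), higher in 3 of 3 libraries. Cluster 12 held 5.57 ± 3.12% and 13.8 ± 3.70% (edgeR BH-adjusted p = 0.177), and the largest, cluster 22, held 25.8 ± 8.50% and 21.5 ± 2.11%.

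Genes fell within single neuron clusters as well. In cluster 22, Chst9 fell by 1.17 (SE 0.11), Lrrtm3 by 0.87 (SE 0.08), the ephrin receptor gene Epha5 by 0.97 (SE 0.08) and Kctd16, an auxiliary subunit gene of the GABA-B receptor, by 0.99 (SE 0.09) on the log2 scale, and edgeR called 449 genes, 310 of them lower. In cluster 12, Chst9 fell by 1.35 (SE 0.10), Kctd16 by 0.97 (SE 0.08) and Cyp7b1, an oxysterol hydroxylase gene, by 0.93 (SE 0.10), among 185 called genes. The mitochondrially encoded genes were lower there as well: 10 of 13 fell, among them mt-Co2 by 0.78 and mt-Cytb by 0.69, both among the leading genes of that cluster, whose cells had a median of 0.63% mitochondrial UMIs (list median -0.71, camera BH-adjusted p = 1.95e-13, adjusted p = 0.456 with an estimated correlation). In cluster 2, Efna5, an ephrin ligand gene, fell by 1.30 (SE 0.11) and the potassium channel subunit gene Kcnab1 by 0.83 (SE 0.08), among 332. In cluster 18, Grin2a fell by 0.49 (SE 0.06) and the sodium-calcium exchanger gene Slc8a1 by 0.53 (SE 0.06), among 184. In cluster 22, edgeR called 134, 99 and 149 genes without Control 1, 2 and 3, and 355, 229 and 194 without Sevoflurane 1, 2 and 3. In cluster 12, it called 81, 56 and 46 without Control 1, 2 and 3, and 177 and 102 without Sevoflurane 1 and 2. Cluster 2 had 174, 214 and 185 without Control 1, 2 and 3, and 243 and 212 without Sevoflurane 1 and 2, and cluster 18 had 43, 13 and 35 without Control 1, 2 and 3, and 229 and 55 without Sevoflurane 1 and 2.

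Clusters 13, 17, 19, 20 and 21 had 36, 127, 70, 88 and 60 called genes, and in the same order 1, 41, 2, 32 and 9 without Control 1, 1, 16, 1, 13 and 6 without Control 2, and 1, 6, 18, 90 and 9 without Control 3. They had 10, 103, 51, 43 and 43 without Sevoflurane 1, 4, 95, 3, 26 and 24 without Sevoflurane 2, and 18, 145, 50, 89 and 38 without Sevoflurane 3. DESeq2 called 290, 235, 203, 182 and 175 in these clusters, and 418 in cluster 18. The highest count in another of the 10 splits was 3 in clusters 2, 12, 13 and 22 and 1 in clusters 17, 18, 19, 20 and 21, and 1 split, the real one, reached the real count in each. Too few splits exist for a share under 0.05.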
